A study of Mus musculus with 16 samples.

How the data were processed

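RNA immunoprecipitated with THOC5 from primary mouse vascular smooth muscle cells was measured in 8 of 16 samples, and the other 8 are inputs. The 4 conditions, with 2 samples each, are growth medium (Ctrl), osteogenic medium (Pi), and osteogenic medium with overexpression of GFP (GFP OE) or of THOC5 (THOC5 OE), per the labels. The RNA was recovered with a Magna RIP kit and depleted of rRNA before library preparation, per the labels' protocols. FastQC, Bowtie2, MACS2, SAMtools and the mm10 build are named, without roles or versions, per the submitters' processing notes. Peaks were annotated with annotatePeaks.pl of HOMER against mm10, per the file headers. The program that called these peaks, its settings and its use of the inputs are not given in the sources used here. Each peak has a score that the authors' caller gave and that was carried into the deposited lists; its scale is not given in the sources used here. It was used to order peaks within a list, and was compared between lists only for a common score floor and for the score steps below. Each list has a single peak width, from 415 to 553 bp, and every peak is written on the plus strand, so no strand was used. The lists were joined to samples by the abbreviation of the condition and the number in the file headers.

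A gene was called bound in a list if at least 1 peak was placed by the deposited annotation in its exons, introns, UTRs, non-coding exons or transcription end. The transcript of the annotation, and not the nearest gene, gave the gene, since these differed in 35.6% to 40.7% of peaks. RefSeq genes of the same mouse build gave symbols and coordinates for 28582 of 28614 transcripts named (99.89%). Percentiles are ranks of the score within a list. The coordinates given for a gene's peak are those of its best peak over all lists, which need not be a list of the comparison. The lists hold 28998 peaks, 1 of them on an unplaced scaffold and 0 on the mitochondrial genome. Reads, inputs and expression were not analysed here, so binding is not corrected for the level of a transcript and the absence of a peak does not show absence of binding.

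Depth was not read from libraries. Scores under 60 are whole multiples of a step (within 0.005 below 10 and 0.05 from 10) in at least 98.4% of cases, where 6.33% to 35.5% would be by chance. The steps are 0.726 and 0.758 in Ctrl, 1.58 and 1.14 in Pi, 0.282 and 0.350 in GFP OE and 0.292 and 0.287 in THOC5 OE. If the score is a count scaled to a common total, which no source says, the depth relative to the lowest list is 2.18, 2.08, 1, 1.38, 5.60, 4.51, 5.41 and 5.51 in that order, and the weakest peak of a list rests on 13 to 40 steps.

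Similarity of lists was the Jaccard index of bound genes, tested by exact permutation over all pairings of the 8 lists (smallest p 0.00952). For each comparison, genes bound in both lists of one condition and neither of the other were counted and set against the other 2 splits of the 4 lists, where the smallest p is 1/3. Genes set apart in 1 condition were those bound in its 2 lists and no other, plus those missing there and present in at least 5 of the other 6, tested over 28 choices of 2 lists (smallest p 0.0357). Ratios of bound genes and shares of peak classes were tested by exact permutation. Of 20 gene groups fixed beforehand, 18 had a bound member: contractile, osteochondrogenic, phosphate and calcification, extracellular matrix, TGF-beta and BMP, Wnt, export, mRNA decay, immediate early, cell cycle, stress response, inflammatory, endothelial, fibroblast, leukocyte, nuclear long noncoding, ribosomal protein and small noncoding genes; histones and the mitochondrial genome had none. They were tested in Ctrl by two-sided Fisher's exact test against genes bound in any list, and between conditions by a two-sided permutation test of the difference in numbers of lists with 100000 draws, with Benjamini-Hochberg adjustment over the groups at 0.05.

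Genes named are Thoc5, the 10 genes bound in all 8 lists with the best lowest percentile, the 10 leading genes per comparison and direction by the same rank (predicted genes without a proper symbol passed over), members of preset groups bound on one side only (at most 6 per group and direction), and up to 4 bound members per group; others are said to be chosen after their values were seen. Outside this rule and with their values known, Col4a1, Gphn, Syne1 (most peaks), genes in which a peak named for another gene lies, and members of preset groups without a peak (Myh11, Cnn1, Myocd, Sox9, Spp1, Alpl, Malat1 and Neat1) were named too, as were Clip2 and Grik5, which are all genes of their overlap. Some genes that this rule names are not reported here. Alternatives were a stricter score threshold (the median of each list), lists cut to 2572 peaks, the authors' nearest gene, exons and UTRs only, no unplaced scaffolds, other measures of overlap (1 base, or 50% of both peaks), leaving out each list, a replicate block, Fisher's exact test of genes on each side and a background of Ctrl genes. Added after the data had been seen were a common score floor of 29, any overlap with a gene's span, the exclusion of peaks on rRNA repeats, and pairing of lists only within the 4 vector lists and within the other 4 (9 pairings). The counts of genes on one side, the gene group test between conditions and the similarity test were tested on simulated data drawn from the real frequencies. The exact test over strata was compared with Fisher's exact test on random tables of 1 stratum, and the other tests were not simulated. In the simulations, of 200 planted genes 100% were recovered. They were planted with the pattern that is counted, so this checks the counting and is no measure of sensitivity. Planted group effects were found in 62% to 70% of 50 simulations per comparison, and 2% to 6% of null groups were called. These percentages are for groups of 20 members with 5 planted, and do not give the power of calls adjusted over the groups. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.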

Results

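Thoc5 itself, the overexpressed target, carried 1 peak in Ctrl replicate 2 and no peak in Ctrl replicate 1, in either list of osteogenic medium (Pi), in either list of cells overexpressing GFP (GFP OE) or in either list of cells overexpressing THOC5 (THOC5 OE). That peak lies at chr11, 4924419 to 4924834, in intron 17 of 19, at percentile 3.7 of its list by the authors' score. The peak lists give no level of the transgene. THOC5 is a subunit of the THO complex, which joins transcription to export of mRNA from the nucleus. The 8 lists come from THOC5 immunoprecipitates of RNA from primary mouse vascular smooth muscle cells, 2 lists per condition, and ask which transcripts THOC5 binds as the cells are driven towards an osteogenic state by high phosphate. Nothing in the labels says that the replicates are separate cultures, so every p from a permutation of lists measures only the spread between these samples. Fisher's exact tests and the tests of gene groups take genes as units, and their p do not measure the spread between lists.

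Of the 400 genes bound in all 8 lists, 10 are named by their lowest percentile. Dst, which encodes a linker of the cytoskeleton, held the top percentile (100) in each list, with its peak at chr1, 34228226 to 34228764, in exon 52 of 93, and 10 to 20 peaks per list. Nisch (chr14, 31177009 to 31177482, exon 16 of 21) reached percentiles of 99.8 to 100, and Prrc2c (chr1, 162697679 to 162698217, exon 19 of 35) 99.7 to 99.9. Next came the spectrin gene Sptbn1 (chr11, 30138654 to 30139192, exon 13 of 31; 99.6 to 99.9), Cemip (gene at chr7, 83932857 to 84086693; 99.5 to 99.8) and the dynein heavy chain gene Dync1h1 (chr12, 110617886 to 110618424, exon 8 of 77; 99.4 to 99.8). Fat1 (gene at chr8, 44933100 to 45052257; 99.1 to 100), Zfhx3 (chr8, 108793489 to 108794027, exon 2 of 10; 99.0 to 99.5), the mRNA export gene Zc3h11a (chr1, 133621025 to 133621563, 3' UTR; 99.0 to 99.5) and Nav2 (chr7, 49452655 to 49453193, exon 7 of 38; 98.8 to 99.7) complete them. For Cemip and Fat1 the best peak is not at the same place in all lists. The score is the authors', and percentiles order peaks within a list.

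In total 4051 genes were bound in at least 1 list, 9.87% of them in all 8 and 1507 in 1 list only. Lists held 2572 to 4795 peaks and 1231 to 2093 bound genes. Bound genes were long: the median span was 47970 bp for bound protein-coding genes and 17150 bp for all protein-coding genes, and it went from 27790 bp for genes of 1 list to 111100 bp for genes of all 8. A peak anywhere in a gene, introns included, made it bound, so long genes are called more readily. These spans were not set against randomly placed peaks, so they do not show a preference of THOC5 for long genes. Syne1 (chr10, 5020192 to 5550692) held the most peaks, 45 per list on average (SD 9.86, n = 8). Introns took 52.2% of peaks in Ctrl (SD 0.799, n = 2), 55.5% in Pi (SD 1.80), 58.8% in GFP OE (SD 3.86) and 59.6% in THOC5 OE (SD 0.646), exons 34.6% (SD 1.78), 30.5% (SD 0.822), 28.7% (SD 3.53) and 27.5% (SD 1.23). No class of peak set the groups apart past a Benjamini-Hochberg threshold of 0.05 over all pairings of the lists. The smallest raw p was that of intergenic peaks (exact permutation p 0.0476, adjusted 0.305). Their share was 0.745% in Ctrl, 1.66% in Pi, 1.38% in GFP OE and 1.5% in THOC5 OE. Pi lists held 17 and 28 peaks on rRNA repeats, of which 5 and 8 lay inside genes. How much the others add to the intergenic share of Pi was not tested.

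Among preset groups, Ctrl cells had peaks in both lists on 7 of the 15 bound genes of CCR4-NOT and mRNA decay (odds ratio 2.89, two-sided Fisher's exact p 0.0584, adjusted 0.801) and on 7 of the 17 bound genes of the extracellular matrix (odds ratio 2.31, p 0.0890, adjusted 0.801). None of the 18 preset groups with a bound member passed the adjusted threshold in Ctrl. Smg1, Smg6, Tnrc6a and Xrn1 were bound in all 8 lists, as were the export genes Mcm3ap, Nup98, Thoc2 and Zc3h11a, the matrix genes Col5a1 and Fbn1, the contractile gene Mylk, Ltbp2 of the TGF-beta and BMP group, the Wnt coreceptor gene Lrp6 and the nuclear RNA Firre. In both Ctrl lists 4 export genes (odds ratio 1.65, p 0.492), 3 contractile genes (1.98, p 0.399), 2 TGF-beta and BMP genes (1.65, p 0.629), 2 Wnt genes (1.32, p 0.668), 1 nuclear long noncoding RNA (3.29, p 0.412), 1 fibroblast marker (3.29, p 0.412), 1 phosphate and calcification gene (0.822, p 1), 1 inflammatory gene (1.10, p 1) and 1 ribosomal protein gene (0.410, p 0.695) were bound. By the annotation's names 4 small noncoding RNAs were too (0.570, p 0.367), but their best peaks are centred in other genes. Of these best peaks only that of Mir5101 (chr12, 75909007 to 75909422) reaches its microRNA. Those of Mir6948 and Mir6932 are from THOC5 OE replicate 2 and not from Ctrl. Osteochondrogenic, immediate early, cell cycle, stress response, endothelial and leukocyte genes were bound in both Ctrl lists in no case, and no histone or mitochondrial gene was bound anywhere. Acta2 (chr19, 34251927 to 34252342, intron 2 of 8) was bound in both Ctrl lists and 1 Pi list, while Myh11, Cnn1, Myocd, Sox9, Spp1, Alpl, Malat1 and Neat1 had no peak in any list.

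Lists of the same condition did not share more genes than other lists past the threshold. The mean Jaccard index, the shared part of 2 gene sets, was 0.444 within conditions and 0.395 between them (difference 0.0488, two-sided exact permutation p 0.0667, 7 pairings as far apart, smallest possible p 0.00952). Within conditions it was 0.389 in Ctrl, 0.362 in Pi, 0.456 in GFP OE and 0.568 in THOC5 OE. The Pi pair lay below the mean of Pi with Ctrl (0.381) and with THOC5 OE (0.380). The GFP OE pair lay below all 4 pairs of GFP OE with THOC5 OE (0.491 to 0.516). Replicates of Pi (553 and 439 bp) and GFP OE (420 and 529 bp) also differ most in peak width. Those of Ctrl have 443 and 415 bp, and those of THOC5 OE 473 and 538 bp. Whether width lowered the likeness within Pi and GFP OE was not tested. With lists paired only among those of cells carrying a vector and among the others, which was added later, the difference was 0.00125 (two-sided exact permutation p 1, smallest possible 0.111). In a test added after the indices had been seen, the 4 lists of cells carrying a vector (GFP OE and THOC5 OE) shared more genes with each other (0.506, range 0.456 to 0.568) than with the other 4 (0.371, range 0.334 to 0.413). This excess of 0.135 was the highest of 35 splits (exact permutation p 0.0286, the smallest possible; highest other split 0.0702).

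**Figure D1:**
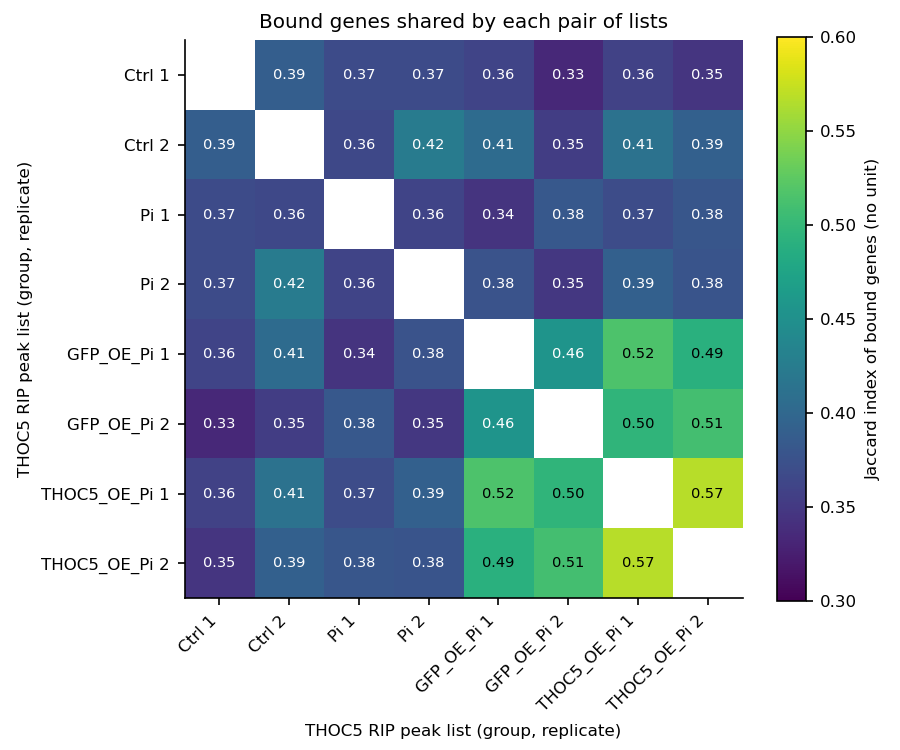
Jaccard index of bound genes for each pair of the 8 peak lists, lists on both axes in the order Ctrl, Pi, GFP OE, THOC5 OE. The vector lists reach 0.456 to 0.568 with each other.

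Osteogenic medium was compared with growth medium to ask which transcripts enter or leave THOC5 binding. Runx2, the master transcription factor of bone formation, was bound in both Pi lists and neither Ctrl list, at chr17, 44735554 to 44735993, in exon 1 of 6 of a non-coding transcript (percentiles 41.7 and 47.9). Among the 4 lists of cells carrying a vector, also in osteogenic medium, only GFP OE replicate 2 had that peak. Bound in both Pi lists and neither Ctrl list as well were Rpl26 (chr11, 68902538 to 68903091, intron 2 of 3), Larp1 (gene at chr11, 57973418 to 58062034; percentiles 86.4 and 91.8), Mia3 (gene at chr1, 183326236 to 183369565; 86.0 and 87.3) and Xpo5 (chr17, 46241948 to 46242501, exon 32 of 32; 85.8 and 85.7). So were Ankrd24 (82.7 and 83.9), Brpf1 (79.9 and 86.1), Usp35 (78.4 and 81.7), Kmt2e (77.6 and 88.0) and Trappc12 (79.7 and 77.4). Among the 4 vector lists Mia3 was bound in 4, Ankrd24, Brpf1 and Kmt2e in 2, Larp1 and Trappc12 in 1, and Xpo5, Usp35 and Rpl26 in 0. Mia3 encodes a receptor for collagen export and Xpo5 the export factor of precursor microRNAs. The highest percentiles belonged to Filip1l (94.1 and 99.2), whose peak at chr16, 57391430 to 57391869, in intron 1 of 4, lies on a repeat that the annotation puts in the rRNA class. Lars2 (chr9, 123461735 to 123462174, 3' UTR; 83.7 and 94.0) had a peak at this place in the 2 Pi lists and no other, with other peaks on the gene in THOC5 OE replicate 1. The place is not annotated as a repeat, and likeness of its sequence to rRNA was not tested.

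Peaks on rRNA repeats numbered 17 and 28 in the Pi lists, 0 and 1 in Ctrl, and 0 in each of the 4 vector lists, which are in the same osteogenic medium. They were looked at after the Pi genes had been seen. Whether rRNA was left in the 2 Pi libraries was not tested, as reads were not analysed here, and the calls of Filip1l, Gphn and Lars2 are not cleared of it. In Pi replicate 2 they made up 6 of the 100 strongest peaks, and 16 of the 17 in Pi replicate 1 overlapped one in Pi replicate 2. Of the genes bound in both Pi lists and neither Ctrl list, Filip1l and Gphn were among those that rested on such peaks. Without these peaks the count was 107 in place of 110.

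Genes bound in both Ctrl lists and neither Pi list were led by a peak named for Mir6948 (percentiles 98.5 and 99.0 in Ctrl). Its place, chr14, 54642388 to 54642926 in THOC5 OE replicate 2, lies inside Acin1 and beside the microRNA, and had a peak in all 4 vector lists. Piezo1, encoding a stretch-gated ion channel (chr8, 122501354 to 122501769, exon 8 of 51; 95.5 and 96.4), Fbxl2 (95 and 97.1), Slc44a2 (93.0 and 94.9), Nktr (92.1 and 93.8), Wsb1 (91.6 and 99.0), Flcn (91.5 and 93.8), Crebzf (89.0 and 94.1), the collagen receptor gene Mrc2 (chr11, 105328155 to 105328570, exon 4 of 30; 87.8 and 91.0) and Zfp516 (87.7 and 91.3) followed. Peaks named for Mir5101 (in Syne2), Mir7064 (in Cars) and Mir6932 (in Helz) showed this pattern too. In total 110 genes were bound in both Pi lists only and 123 in both Ctrl lists only, out of 3384. With full lists, the sum of 233 lies between the 324 and 201 of the other 2 splits of these 4 lists, so the smallest p of 1/3 was not reached. Random lists gave 218 (SD 13.4, 50 simulations), but were drawn over 4051 genes at 1 frequency per gene and with equal expected lengths. That is not a chance level for these 4 lists. Bound genes numbered 1686 in Ctrl (SD 575, n = 2) and 1726 in Pi (SD 262), a ratio of 1.02 (two-sided exact permutation p 1).

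**Figure D2:**
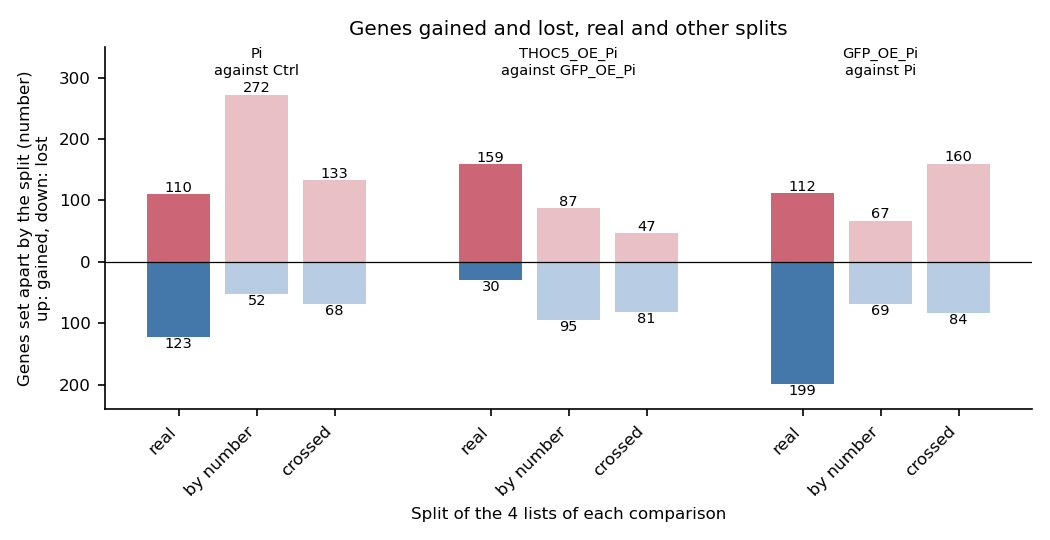
Genes bound in both lists of one side and neither of the other, for the real split and the other 2 splits of each set of 4 lists. For Pi and Ctrl the real split gives 233 genes, the split by replicate number 324 and the crossed split 201.

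No preset group passed the adjusted threshold between Pi and Ctrl. Osteochondrogenic genes had the smallest raw p: the 2 bound members had 1.48 more Pi than Ctrl lists than other genes did (two-sided permutation p 0.0433, adjusted 0.5). The 5 phosphate and calcification genes (excess 0.776, permutation p 0.0926), 17 matrix genes (0.329, p 0.156), 8 contractile genes (0.101, permutation p 0.851) and 9 ribosomal protein genes (0.199, permutation p 0.597) had adjusted p of 0.5, 0.5, 0.95 and 0.94. Genes set apart in growth medium against all osteogenic lists numbered 102, with 60 bound in both Ctrl lists alone and 42 missing there. That number was reached by 4 of 28 choices of 2 lists (one-sided exact permutation p 0.143), and Ctrl replicate 1 with Pi replicate 1 gave 138.

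THOC5 OE was compared with GFP OE, both in osteogenic medium, to ask what more THOC5 adds to the bound set. Tulp4 (chr17, 6138352 to 6138890, 5' UTR; percentiles 99.0 and 99.1), the coatomer gene Copa (chr1, 172121471 to 172122009, exon 33 of 33; 96.3 and 96.5), the kinase gene Dapk1 (chr13, 60761022 to 60761560, exon 26 of 26; 96.3 and 96.8) and the laminin gene Lama5 (gene at chr2, 180176373 to 180225904; 96.0 and 95.9) were bound in both THOC5 OE lists and neither GFP OE list. So were Rbm5 (95.8 and 95.5), Atf7ip (95.1 and 95.7), Map4 (94.3 and 94.9), Irak1 (92.7 and 93.1), Nod1 (94.1 and 91.7), Arhgef40 (91.2 and 91.8) and the replication gene Mcm6 (chr1, 128348525 to 128349063, intron 6 of 15; 17.3 and 18). Lama5 and Nod1 were bound in all 4 Ctrl and Pi lists. Tulp4, Dapk1, Rbm5 and Arhgef40 were bound in 5 lists, among them Ctrl and Pi lists. All of these were thus set apart by lacking a peak in GFP OE, and not by being bound in THOC5 OE alone. Copa, Atf7ip, Map4 and Irak1 were bound in 3 lists, which include a Ctrl or Pi list. Among the genes named in this direction, only Mcm6 was bound in THOC5 OE lists alone. In the other direction, Marchf7 (96.2 and 78.9 in GFP OE), the integrin gene Itgb1 (chr8, 128713409 to 128713848, intron 5 of 15; 71.5 and 75.2), Zfp715 (56.7 and 86.9), Mlh3 (57.2 and 55.8), Slit3 (55.4 and 62.2), Zup1 (65.9 and 51.9), Shroom1 (43.5 and 52.9), Gcfc2 (60.2 and 42.8) and Sec24c (38.6 and 41.3) were bound in both GFP OE lists and neither THOC5 OE list. Timm10b was as well (60.5 and 48.3), although peaks at that place, which Dnhd1 shares, were in both THOC5 OE lists.

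In all, 159 genes were bound in both THOC5 OE lists only and 30 in both GFP OE lists only, of 2509. The sum of 189 was above the 182 and 128 of the other splits (smallest possible p 1/3). Random lists gave 222 (SD 12.7), but were drawn over 4051 genes at 1 frequency per gene for all conditions. They keep neither the likeness nor the lengths of these 4 lists, so 222 is not a chance level for 189. THOC5 OE lists held 1668 bound genes (SD 27.6, n = 2) and GFP OE lists 1327 (SD 136), a ratio of 1.26 (two-sided exact permutation p 0.333, the smallest possible). With every list cut to 2572 peaks the counts were 56 and 51 and the ratio 0.914, and their sum of 107 was below the 126 of the split by replicate number. Csmd1 (chr8, 15892538 to 17535385), chosen after its values were seen, held 28 and 27 peaks in THOC5 OE, 4 and 0 in GFP OE, 19 and 31 in Ctrl and 19 and 28 in Pi. No preset group passed the adjusted threshold: 4 Wnt genes had the smallest raw p (excess -1.02, two-sided permutation p 0.0213, adjusted 0.320), then 2 ribosomal protein genes (-1.27, permutation p 0.0482, adjusted 0.362). Genes set apart in THOC5 OE numbered 83 (66 bound there alone, 17 missing there), a number reached by 7 of 28 choices (one-sided exact permutation p 0.25).

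GFP OE was compared with Pi, which share the medium, to ask what the vector and its experiment bring. Ext1 (chr15, 53344939 to 53345354, exon 1 of 11; percentiles 97.1 and 97.0 in Pi), which makes heparan sulfate, and Rusc2 (chr4, 43415542 to 43415981, exon 2 of 12; 96.0 and 97.7) were bound in both Pi and both Ctrl lists and in no vector list. Chd4 (98.5 and 98.4), Filip1l, Lama5 (99.2 and 93.7), Shroom3 (96.7 and 92.1), Pcnx3 (93.4 and 91.9) and peaks named for Wdr34 (in Sptan1; 98.7 and 98.9) and Srebf1 (in Rai1; 91.6 and 90.8) were likewise in both Pi lists and neither GFP OE list. Bound in both GFP OE lists and neither Pi list were Parg (chr14, 32208974 to 32209447, exon 3 of 18; 92.8 and 91.8), Zfyve16 (92.3 and 89.3), Dhx57 (86.0 and 85.5), Limk2 (chr11, 3344856 to 3345385, 3' UTR; 79.9 and 82.9), Marchf7 (96.2 and 78.9), Npat (75.3 and 74.0), Eif4ebp3 (73.7 and 71.7) and peaks named for Mir6948 (in Acin1) and Mir7026 (in Ep400; 81.6 and 84.6). In total 112 genes were bound in both GFP OE lists only and 199 in both Pi lists only, of 3065. These counts were 54 and 196 at the common score floor, and 74 and 152 with every list cut to 2572 peaks. The sum of 311 exceeded the 136 and 244 of the other splits (smallest possible p 1/3), but with every list cut to 2572 peaks it was 226, below the 237 of the crossed split. Random lists, simulated without this limit and over 4051 genes at 1 frequency per gene, gave 222 (SD 13.3). That is not a chance level for the 311. The ratio of bound genes was 0.769 (two-sided exact permutation p 0.333).

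A test of gene groups on GFP OE and Pi was added after the bound genes had been seen. Cell cycle genes were bound in 1.51 more GFP OE than Pi lists than other genes were (4 members, two-sided permutation p 0.00240, adjusted 0.0384), with 4, 1, 3 and 4 members bound in the vector lists against 0, 2, 0 and 0 in the others. Kif20b was bound in all 4 vector lists and no other. The call rests on 4 genes and was not kept with lists cut to 2572 peaks (excess 1.23, permutation p adjusted 0.641), nor under most other settings. Matrix genes lay on the other side (17 members, excess -0.622, p 0.00746, adjusted 0.0597), with 9 and 10 members in Ctrl, 12 and 13 in Pi, 5 and 5 in GFP OE and 7 and 6 in THOC5 OE. Contractile genes (7 members, excess -0.597, permutation p 0.120, adjusted 0.352) and ribosomal protein genes (7 members, -0.597, permutation p 0.120, adjusted 0.352) did not pass either. The phosphate carrier gene Slc20a1 (gene at chr2, 129198773 to 129211615), Col4a1, Gsn, Axin1 and Rps26 were bound in all 4 Ctrl and Pi lists and no vector list. Across the 8 lists 44 genes were bound in the 4 vector lists alone and 28 in the other 4 alone. The highest other split gave 16, and the 28 was reached by 1 of 35 splits (one-sided exact permutation p 0.0286). The split into vector and other lists had been picked from the indices of the same lists, so this p is no separate support for it. Hmcn1, chosen after its values were seen, held 21, 14, 21 and 23 peaks in the vector lists and 0, 3, 0 and 2 in the others. These lists also stand apart in the median span of their bound genes, 80160 to 82550 bp against 58620 to 66240 bp in Ctrl and Pi, and in the step between scores, 0.282 to 0.350 against 0.726 to 1.58.

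**Figure D3:**
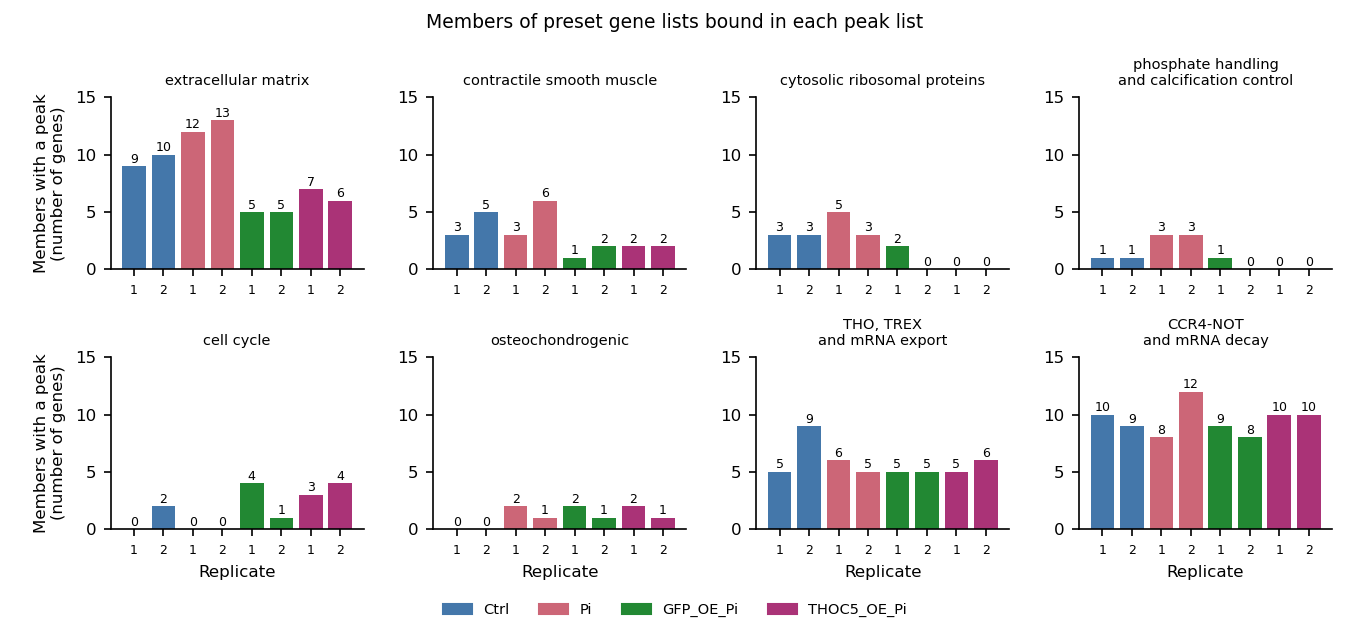
Members of preset gene groups bound in each of the 8 lists, by condition. Matrix genes number 9 to 13 in Ctrl and Pi and 5 to 7 in the vector lists.

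**Figure D4:**
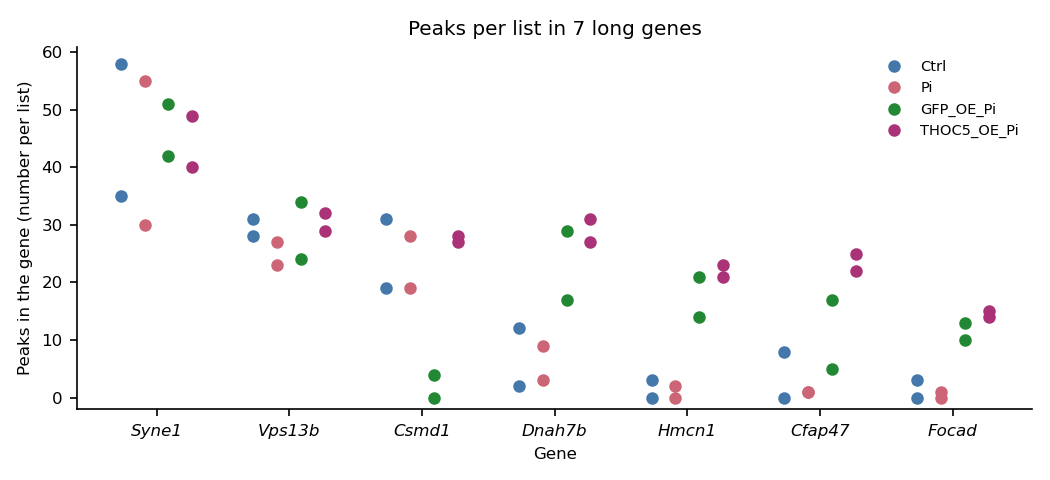
Peaks per list on genes with many peaks, including Syne1, Csmd1 and Hmcn1, by condition. Csmd1 has 4 and 0 peaks in GFP OE and 28 and 27 in THOC5 OE.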

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

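With 2 lists per condition no count between 2 conditions can reach a p below 1/3, and lists of unequal length limit every count. The common score floor, the overlap with a gene's span the exclusion of rRNA repeats and the pairing within vector and other lists were chosen after seeing the data. No called result changed sign, but directions without a call did, among them the ratios and exon shares below and the Pi to Ctrl ratio (1.02, by exons and UTRs 0.889). At the stricter score threshold the counts of genes on one side only were 114 for Pi and Ctrl, 94 for THOC5 OE and GFP OE and 160 for GFP OE and Pi, genes set apart were 47 in Ctrl and 33 in THOC5 OE, and the exon share of Pi minus Ctrl was -6.51 points; fewer peaks are left by construction. With lists cut to the shortest, THOC5 OE and GFP OE gave 107 genes and a ratio of 0.914, genes set apart in THOC5 OE were 21, and exon share differences were -5.66 (Pi minus Ctrl) and 2.02 points (THOC5 OE minus GFP OE, -1.20 with all peaks). The exon share of GFP OE minus Pi, -1.74, was 0.269 at the stricter score and 0.441 at the common floor. Exons and UTRs alone gave 175 genes for GFP OE and Pi and 61 set apart in Ctrl. The common floor gave 44 set apart in THOC5 OE and a GFP OE to Pi ratio of 0.645. Peaks in place of genes gave ratios of 1.41 (THOC5 OE to GFP OE) and 0.973 (GFP OE to Pi). The similarity difference between same-condition and other pairs passed the threshold at the stricter score (0.0531), by nearest gene (0.0462), by exons and UTRs (0.0524), at the common floor (0.0547) and by gene span (0.0499), and did not with lists cut to the shortest (0.0445, exact permutation p 0.0857), by bases (0.0392, p 0.133), by peaks sharing 1 base (0.0613, p 0.0571) or 50% of both (0.0611, p 0.105), with rRNA repeats excluded (0.0485, p 0.0667) or without unplaced scaffolds (0.0488, p 0.0667). These pairings mix vector with other lists. Paired within each, the difference was 0.00125 (exact permutation p 1) and 0.000815 to 0.0122 under the other settings (p 0.333 to 1). No likeness by condition beyond the vector split is thus shown. It is not excluded either, since the 9 pairings allow no p below 0.111. Leaving out 1 list in turn gave 579 to 845 genes for Pi and Ctrl, 479 to 562 for THOC5 OE and GFP OE, 567 to 1017 for GFP OE and Pi, 117 to 505 set apart in Ctrl and 101 to 258 in THOC5 OE, since 1 list then stands for a condition. No gene group passed in Ctrl, between Pi and Ctrl or between THOC5 OE and GFP OE under any setting. The cell cycle result of GFP OE and Pi, itself added, did not pass with lists cut to the shortest (excess 1.23, adjusted p 0.641), by nearest gene (0.544, adjusted p 0.696), by exons and UTRs (2.25, adjusted p 0.469), as a replicate block (adjusted p 0.0975), by Fisher's exact test (0.972), without either Pi list (excess 1.69 and 1.43, adjusted p 0.122 and 0.235) or without GFP OE replicate 1 (2.35, 0.438), and no member was left to test at the stricter score or the common floor. Against 1.51 with all lists, the excess was thus not much smaller where lists were left out. It passed without scaffolds, by gene span, with rRNA repeats excluded and without GFP OE replicate 2. Of the genes named for Pi and Ctrl, THOC5 OE and GFP OE, and GFP OE and Pi, nearest gene kept the pattern of only 12 of 25, 11 of 21 and 13 of 20, exons and UTRs of 13, 11 and 10, and the other settings of 21 to 25, 16 to 21 and 14 to 20. As a replicate block the ratios were 1.05 (Pi to Ctrl), 1.26 and 0.771, and no planned call changed. Deviations by number correlate at only -0.0724 to 0.0588. GFP OE and THOC5 OE lists of equal number shared more genes (0.516 and 0.511) than those of unequal number (0.491 and 0.496). Between Pi and GFP OE it was the other way (0.345 and 0.349 against 0.383 and 0.377). Whether equal numbers share a preparation was not tested.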

Other observations

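The tests of peak width, of GFP OE against Pi and THOC5 OE, of the strong peaks of Ctrl and Pi lists and of all pools of gene groups were chosen only after the result was seen, as were the test of vector lists itself and the gene group test of GFP OE and Pi. Lists of cells carrying a vector shared more bound genes with each other than with Ctrl or Pi lists. Length of the lists is argued against as the whole source, since with lists cut to the shortest the excess was 0.113 (exact permutation p 0.0286, highest other split 0.0919). The lowest vector pair of unlike width exceeded the highest mixed pair of like width by 0.0506. GFP OE lists were closer to THOC5 OE than to Pi lists by 0.14. Every vector pair (at least 0.456) lay above every mixed pair (at most 0.413), so both signs were fixed by indices already seen. These values describe a split between vector and other lists that followed neither peak width nor THOC5 overexpression, and are not separate tests of either. Likeness still went with width in part. Every Ctrl, Pi and THOC5 OE list shared more genes with the GFP OE list nearer its own width. Pi replicate 1 (553 bp) had an index of 0.383 with GFP OE replicate 2 (529 bp) and 0.345 with GFP OE replicate 1 (420 bp). Depth was not decided by its planned test (500 strongest peaks, 7.70 points, exact permutation p 0.257, 9 of 35 splits). In a later test, strong peaks of the Ctrl and Pi lists were found in each other's lists 7.34 points more often than in the vector lists (5.12 to 10.3 points in each of the 4 lists). The summed excess was the highest of 35 splits (exact permutation p 0.0286), but this split was picked from the same lists. Greater depth would make such peaks easier to find in the vector lists, so the test speaks against depth only if those lists are deeper. Their depth rests on the score steps alone, on a scale that no source gives, so depth stays open. Carrying a vector and a separate experiment or preparation stay open too, since the labels give no culture, day or batch.

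Ctrl and Pi lists were set apart by fewer genes (233) than the same lists split by number (324). With lists cut to the shortest the difference was -12 genes (185 against 197), within its counting spread of 39.1, in place of -91. The limit first written, any value below 0, was wrong in that it ignored this spread, and was replaced after the value had been seen. Unequal list lengths and a small effect of the medium cannot be told apart here, as 2 lists per condition are too few. No biological explanation was tested beyond the medium itself.

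Matrix, contractile and ribosomal protein genes were bound in fewer GFP OE than Pi lists, relative to other genes, but no group passed on its own (adjusted p 0.0597, 0.352 and 0.352). The 3 groups were pooled because their counts had been seen to be low, so the pool was also set against the most extreme of 696 pools of 1 to 3 groups in each shuffle, and with full lists it did not pass that (31 members, excess -0.610, permutation p 0.0800). With lists cut to the shortest it did (excess -0.661, permutation p 0.00028, with this allowance 0.0292). This argues against list length as the whole source of the low counts, but does not make up for the full lists, where the pool did not pass. Against genes of like span the excess was little smaller, -0.554 (permutation p 0.00117), but with the allowance p was 0.140. The limit first written for list length and for gene length, a p of at most 0.05 for the pool, was wrong in leaving the picking out. It was replaced after the values had been seen. Gene length, chance in the picking, a vector effect and a separate preparation stay open, and transcript levels were not analysed here.

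Overexpression of THOC5 restores what Pi removed, as a hypothesis, if genes that leave binding with Pi return with THOC5. Of 63 genes bound in both Ctrl and neither Pi list and 93 bound in both THOC5 OE and neither GFP OE list, among 1842 genes testable in both, 2 were shared (Clip2 and Grik5), where independent lists would share 3.18 (odds ratio 0.608, one-sided 95% upper bound 2.03, one-sided Fisher's exact p 0.839). These counts are too few to decide it, since an odds ratio of 2.03 is not excluded. The limit first written against it needed a one-sided 95% lower bound that did not exclude independent lists, and an overlap within 1.5 times of them. It was tightened after the value had been seen because it left the spread up to 2.03 out.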
